A study of Mus musculus with 10 samples.

How the data were processed

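Gene expression was measured in whole skin of C57BL/6 mice at 5 months of age. The 10 libraries fall into 2 genotype groups by their titles: 5 from mice in which STAT3 was ablated in keratinocytes (STAT3cKO) and 5 from wild-type mice (WT). Per the labels' protocols, total RNA was extracted with Trizol and sequenced with the Lexogen QuantSeq kit, which reads the 3′ end of polyadenylated transcripts, so that the number of reads follows the number of transcripts and not their length. Sex, litter, harvest time, hair growth phase and sequencing batch are not given in the sources used here. Nor do they say that each library came from a separate mouse, so the p-values measure the spread between these libraries, part of which may be technical.

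The authors deposited 1 table per library with a value per gene symbol. Per the submitters' processing notes, reads were processed with Bowtie2 and bedtools against the mouse build mm10. The versions, the gene annotation, the use of strand, the scaling and the treatment of duplicate reads are not given in the sources used here. The file headers name no unit, and the unit was read from the values. The deposited values behave as log2 of reads per gene plus a pseudocount of 1, after the reads had been brought to a similar library size: undoing the log gave sums of 9690000 to 11400000 per library. The sums were 10800000 to 11400000 in WT and 9690000 to 10700000 in STAT3cKO. They were thus not the same total in each library, and the groups did not overlap in them. Within each library, low values lay near multiples of 1 step, the worth of a single read. Among values of up to 20 reads, 88.8 to 100% came out whole within 0.15 of a read. Dividing each sum by its step gave estimated depths of 7130000 to 18500000 reads. In 6 libraries genes without a read carried values slightly above 0, of up to 0.08, and a value below that of 0.5 of a read was taken as no read. No molecular identifiers are named, so duplicate reads could not be told from separate molecules, and the depth describes counting error only.

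Each table holds 23282 entries, of which 5996 were at 0 in every library. A symbol that had occurred before was repeated in 44 entries, which were kept as entries of their own, and gene lists used the earlier one. A gene was tested when its value was at least 5 in at least 5 libraries, which left 11536 genes. The design fixed before the data were examined assumed raw counts and a count model. Because the deposited values were scaled and logged, a linear model was fitted to them with limma 3.58.1 in R 4.3.3 (group as the only term, empirical Bayes moderation with a mean trend and robust estimation). Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. All adjusted p-values for genes are from limma. All changes are STAT3cKO minus WT on the deposited log2 scale. Its pseudocount understates changes of genes with few reads in every library. A library without a read can instead enlarge the change of a gene that has many reads in others. The change of Acot5, with no read in 3 WT libraries, was 7.42 and ranged from 2.45 to 8.72 over the alternatives given below. Errors of group means are SDs, those of changes are standard errors, and intervals are at 95%. Exact 2-sided permutation tests over the 252 ways to assign 5 of 10 libraries were used for single values, and their smallest p is 0.00794.

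The 35 gene lists (16 of skin biology and 19 of cell type markers) were fixed together with the design, and 9 symbols stand in more than 1 list. The 32 lists with at least 5 tested members entered limma's camera test at a preset correlation of 0.01, with adjustment over the lists. Camera with an estimated correlation and limma's fry were run beside it. The preset test is liberal in these data: in other splits of the 10 libraries it called a median of 10 lists. The rule for named genes took Stat3, Spink5 and Klk5, the genes of the study's title. To these it added the 10 largest changes in each direction among called genes with non-overlapping groups and a mean of at least 10 reads, up to 4 called members per list, and up to 2 members with the lowest p from a list with none. Predicted genes were counted but not named. Called genes whose change is given outside the rule are marked as chosen after their values were seen. Results for some genes are not reported here.

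Gene positions come from the GENCODE mouse annotation, release 21 of its M series, on the same build. For 96.4% of the tested entries it holds exactly 1 gene of that name. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

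The steps were tested on simulated data with the spread of these libraries, in which 200 of the 11536 genes had been changed. Of 50 genes changed by 1 on the log2 scale 0 were called, of 50 changed by 2 6 were called, of 50 changed by 3 16 were called, and of 50 changed by 5 20 were called. Among changed genes with a mean value of at least 9, the calls were 0 of 8, 5 of 13, 11 of 13 and 9 of 10 at these sizes. Of the 11336 unchanged genes 1 was called. The list that had been raised was called, and 0 of 30 unchanged lists were. Each gene was shuffled on its own, which removed the correlation between genes. The simulation therefore does not show how often the list test calls falsely in these data.

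The alternatives tried were median-of-ratios scaling, a trimmed-mean scaling that left out 6 tissue lists, array quality weights, no filter, a filter at 10 scaled reads, moderation without robust estimation, a stricter threshold of 0.01, a minimum 2-fold change, the replicate number as a block, and each library left out in turn. Chosen after the values were seen were pseudocounts of 10 and 100, a filter at a value of 7, depth class or the mean of the hair shaft list as a covariate, quantile normalization, and a fit without STAT3cKO 2 and WT 3. No library or gene above the filter was left out of the comparison itself.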

Results

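The data are 10 libraries of 3′ transcript ends from whole mouse skin, 5 STAT3cKO and 5 WT. STAT3 is a transcription factor that cytokine and growth factor receptors activate through Janus kinases. The estimated depth, to 3 significant digits, was 16800000, 14400000, 8370000, 9520000 and 7130000 reads in WT 1 to 5 and 7890000, 7450000, 9930000, 14200000 and 18500000 reads in STAT3cKO 1 to 5. Both groups held deeper and shallower libraries. The number of tested genes without a single read was 2617 of 11536 in STAT3cKO 2 and 1273 in WT 3, against 83 in WT 4. Of genes whose median in the other 9 libraries lay between 7 and 8, 30.1% had no read in STAT3cKO 2, 11.7% had none in WT 3 and 0.265% had none in WT 4. Depth alone does not give these numbers, since WT 5 had fewer reads than STAT3cKO 2 and 983 tested genes without a read, and STAT3cKO 1 had a similar depth and 415. In STAT3cKO 2 and WT 3 no read of a gene is therefore weak evidence that its transcript was absent.

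STAT3cKO 2 was also the library that carried Ddx3y, a gene of the Y chromosome, at 10.6 and lacked Xist, the RNA of the inactive X chromosome, at 0.064. The other 9 libraries had Xist at 8.65 to 11.01 and Ddx3y at no more than 1.26, the level of about 1 read. The other Y genes looked at, Eif2s3y, Uty and Kdm5d, had no read in STAT3cKO 2 (values of 0.01, 0.02 and 0) and at most 1.36 in the other libraries, so Ddx3y was the only one of the 4 Y genes that STAT3cKO 2 carried. Pearson's r across genes ranged from 0.457 to 0.737 over pairs of libraries, with a median of 0.585 within and 0.526 between the groups. Genes are not independent replicates, so these values only describe the likeness of libraries.

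The comparison of STAT3cKO with WT skin addresses the study's title question, whether loss of STAT3 in keratinocytes alters the skin barrier through SPINK5 and KLK5. Klk5, a trypsin-like protease that cuts the desmosomal links between cornified cells, rose 3.78-fold in STAT3cKO skin. Its inhibitor Spink5, the gene of Netherton syndrome, did not pass the test. The rises included Hrnr, a gene of the cornified envelope, by 3.40 on the log2 scale (SE 0.37, n = 5 in each group), Slc27a4 of the epidermal lipid barrier by 3.14 (SE 0.38) and the immediate early gene Fos by 6.83 (SE 0.96). The falls included 16 major urinary protein genes and Rnase2a, which had no read in STAT3cKO skin. In total 61 genes rose and 53 fell, 0.988% of the 11536 tested, and each of the 114 changed by at least 2-fold.

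Stat3 (chromosome 11, 100885098 to 100939540, minus strand of mm10) had a value of 9.72 ± 0.56 (SD, n = 5) in WT and 10.13 ± 0.48 in STAT3cKO. The change was 0.41 (SE 0.36, 95% interval −0.35 to 1.17, limma adjusted p = 0.700). The deleted exons are not given in the sources used here, 3′ reads can come from a transcript that lacks them, and whole skin holds many cells other than keratinocytes, so this level checks nothing about the ablation. Spink5 (chromosome 18, 43963235 to 44022501, plus strand) was abundant in both groups, 12.86 ± 0.61 in WT and 13.28 ± 0.30 in STAT3cKO. Its change was 0.42 (SE 0.29, 95% interval −0.19 to 1.02, limma adjusted p = 0.607). For the level in whole skin the interval left room for a rise of up to 1.02 and excluded a fall beyond −0.19. The mean of the terminal differentiation list was higher by 1.46 in STAT3cKO, and a change of Spink5 relative to those genes was not tested. Among the 4 deeper libraries alone the change of Spink5 was 0.90 (SE 0.32, unadjusted p = 0.0195, limma adjusted p = 0.308), and among the 6 shallower ones it was 0.09 (SE 0.36, limma adjusted p = 0.973).

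Klk5 (chromosome 7, 43841971 to 43851181, plus strand) went from 8.88 ± 0.64 to 10.80 ± 0.61 (SD, n = 5 each), a change of 1.92 (SE 0.39, 95% interval 1.09 to 2.75, limma adjusted p = 0.0223). All 5 STAT3cKO libraries lay above all 5 WT libraries. Among the 4 deeper libraries alone the change was 2.16 (SE 0.45, limma adjusted p = 0.0694), and among the 6 shallower ones it was 1.76 (SE 0.49, limma adjusted p = 0.375). The call was lost without STAT3cKO 1 (1.66, adjusted p = 0.0878), without WT 1 (1.69, adjusted p = 0.0729) and without WT 2 (1.83, adjusted p = 0.0606). Klk5 and Spink5 stand in the study's title, so the lists that hold them are not independent evidence of a direction.

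**Figure D1:**
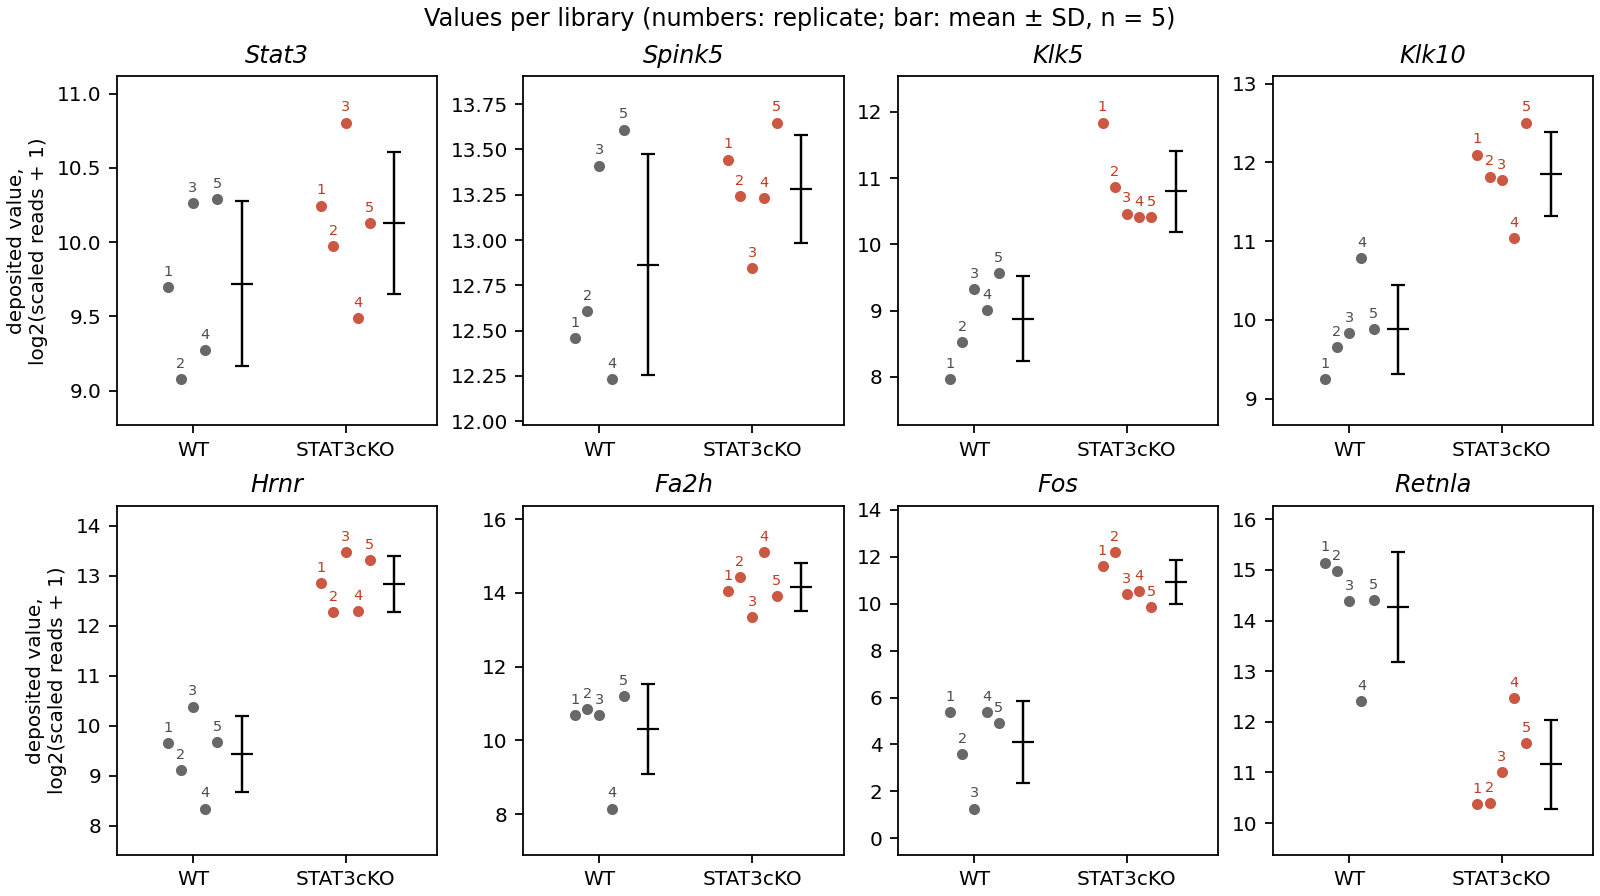
Deposited log2 value (scaled reads plus 1) on the y axis of 8 genes in each library, 1 point per library with its replicate number, WT beside STAT3cKO, with the mean ± SD (n = 5) as a bar; the y axes do not start at 0. The STAT3cKO points of Klk5, Klk10, Hrnr, Fa2h and Fos lie above all WT points, and those of Stat3 and Spink5 overlap with WT.

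Of 12 tested members of the list of epidermal kallikreins and serine proteases 2 rose, 0 fell and 10 did not pass. Adjusted over the list alone, 5 were higher and 1 was lower. Beside Klk5 the other riser was Klk10 (chromosome 7, 43781035 to 43785410, plus strand), a neighbouring kallikrein, by 1.97 (SE 0.34, limma adjusted p = 0.00622). The median change of the list was 0.99 (camera adjusted p = 4.38e-04 at the preset correlation). With an estimated correlation its adjusted p was 0.15. Of 14 epidermal protease inhibitors 0 passed over all genes and 5 were higher adjusted over the list alone, with a median of 1.14. The adjusted p was 7.42e-06 at the preset and 0.15 with an estimated correlation. Wfdc5, a secreted whey acidic protein domain inhibitor, had a change of 1.48 (limma adjusted p = 0.0910) and Csta1, a cystatin, one of 1.05 (limma adjusted p = 0.125).

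Of 31 tested genes of terminal differentiation and the cornified envelope 3 rose, 0 fell and 28 did not pass, but 30 of the 31 had a positive change and 14 were higher adjusted over the list alone. Hrnr (chromosome 3, 93319749 to 93333570, plus strand), which encodes the filaggrin-like protein hornerin, rose 10.6-fold, from 9.43 ± 0.76 to 12.84 ± 0.56 (3.40, SE 0.37, limma adjusted p = 0.000122). Ppl, the cornified envelope protein periplakin, rose by 1.39 (adjusted p = 0.0273) and Slurp1, a secreted protein of keratinocytes, by 3.40 (adjusted p = 0.0324). The call of Ppl held in 4 and that of Slurp1 in 5 of the 10 fits that each left out 1 library, and the highest adjusted p was 0.0960 for Ppl without WT 1 and 0.143 for Slurp1 without STAT3cKO 1. The list's median was 1.21 (camera adjusted p = 1.36e-15 at the preset correlation). Its adjusted p was 0.126 with an estimated correlation, and 0.0356 by fry.

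Of 17 small proline-rich and late cornified envelope genes 2 rose, 0 fell and 15 did not pass, with 8 higher adjusted over the list alone. Lce1g rose by 3.96 (SE 0.76, limma adjusted p = 0.0146) and Lce6a by 2.19 (SE 0.45, limma adjusted p = 0.0220). Each call held in 7 of the 10 fits without 1 library. That of Lce1g was lost without WT 3, STAT3cKO 1 or STAT3cKO 5 (adjusted p up to 0.0713), and that of Lce6a without WT 2, STAT3cKO 1 or STAT3cKO 5 (adjusted p up to 0.0848). The list had a median of 1.51 and a camera adjusted p of 6.45e-11, or an adjusted p of 0.135 with an estimated correlation.

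The list of the epidermal lipid barrier, whose genes make and move the ceramides and fatty acids between cornified cells, passed with either correlation. Of 23 tested members 3 rose, 0 fell and 20 did not pass, with 5 higher adjusted over the list alone and a median of 1.09. The camera adjusted p was 4.63e-10 at the preset and 0.0205 with an estimated correlation. Slc27a4 (chromosome 2, 29802634 to 29817522, plus strand), the fatty acid transport protein whose loss gives newborn mice a wrinkle-free, leaky skin, rose 8.82-fold, from 8.71 ± 0.81 to 11.85 ± 0.40 (3.14, SE 0.38, limma adjusted p = 0.000276). Fa2h, the fatty acid 2-hydroxylase, rose by 3.85 (SE 0.53, limma adjusted p = 0.00260) and Elovl4, which elongates very long fatty acids, by 2.03 (SE 0.34, limma adjusted p = 0.00397). The calls of Slc27a4, Fa2h and Elovl4 held with any 1 library left out. Cers4, a ceramide synthase outside the fixed lists and chosen after its value was seen, rose by 2.74 (limma adjusted p = 0.000684). Whether these rises came from the epidermis or from follicles and sebaceous glands was not tested, since whole skin mixes them.

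Of 25 cell junction genes 0 passed over all genes and 5 were higher adjusted over the list alone, with a median of 1.04 (camera adjusted p = 3.50e-05 at the preset and 0.358 with an estimated correlation). Perp, a desmosomal protein, had a change of 1.1 (limma adjusted p = 0.101) and Dsp, desmoplakin, one of 0.88 (limma adjusted p = 0.107). Basal keratinocyte genes stayed closer to no change: 0 of 15 passed on either adjustment and the median was 0.37. The list's adjusted p of 0.0212 at the preset correlation became 0.426 with an estimated correlation, and the call was also lost without WT 1, WT 2, STAT3cKO 1 or STAT3cKO 3 (adjusted p up to 0.117). Krt14 had a change of 1.30 (limma adjusted p = 0.25) and Itgb1, an integrin of the basal layer, one of −0.87 (limma adjusted p = 0.262).

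Of 17 genes of activated keratinocytes and antimicrobial defence 1 rose over all genes and 1 adjusted over the list alone, while the change was positive for 17 of 17, with a median of 2.26 (camera adjusted p = 4.33e-07 at the preset and 0.133 with an estimated correlation). The riser was Il1f5, also called Il36rn, the antagonist of the interleukin 36 receptor, by 2.26 (SE 0.46, limma adjusted p = 0.0207). Its call held in 6 of the 10 fits without 1 library and was lost without WT 1, WT 2, STAT3cKO 1 or STAT3cKO 5 (adjusted p up to 0.0826).

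The list of immediate early and heat shock genes, which cells switch on within minutes of a stimulus, also passed with either correlation. Of 17 tested members 5 rose, 0 fell and 12 did not pass, and 11 were higher adjusted over the list alone. The median was 1.90 and the camera adjusted p was 8.23e-13 at the preset and 0.00200 with an estimated correlation. Fos (chromosome 12, 85473890 to 85477273, plus strand) rose from 4.10 ± 1.75 to 10.93 ± 0.95 (6.83, SE 0.96, limma adjusted p = 0.000762). Ier3 rose by 1.92 (adjusted p = 0.0132), Jun by 2.16 (adjusted p = 0.0293), Junb by 1.77 (adjusted p = 0.0186) and Dusp1, named after its value was seen, by 1.98 (adjusted p = 0.0339). The calls of Fos and Ier3 held with any 1 library left out, that of Junb was lost without WT 2 (adjusted p = 0.0531), and those of Jun and Dusp1 held in 4 of the 10 fits each, for Jun with a highest adjusted p of 0.0884 without WT 1. The exons of Jun, Junb and Dusp1 overlap those of a gene on the other strand, and the sources used here do not say whether reads were counted by strand.

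Of 18 tested STAT3 target genes 1 rose, Junb, 0 fell and 17 did not pass, with 3 higher adjusted over the list alone and a median of 0.67. The camera adjusted p was 1.02e-04 at the preset and 0.15 with an estimated correlation. Among 19 JAK-STAT components 0 passed and the median was 0.11 (camera adjusted p = 0.417).

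The 16 tested circadian clock genes had 0 calls, a median of 0.79 and a camera adjusted p of 0.0176 at the preset, which became 0.219 with an estimated correlation and was lost without WT 1 or WT 4 (adjusted p up to 0.0532). Per2, a repressor of the clock, had a value of 2.16 ± 2.91 in WT, where 3 of 5 libraries had no read, and 7.71 ± 1.52 in STAT3cKO (SD, n = 5, limma adjusted p = 0.157). Of 20 cell cycle genes 0 passed, with a median of 0.52 (camera adjusted p = 0.0736). Cdk1 had a change of 1.96 (limma adjusted p = 0.341).

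Of 13 tested genes of type 2 and allergic inflammation 2 fell, 0 rose and 11 did not pass, with 3 lower adjusted over the list alone and a median of −1.1. The camera adjusted p of 0.0116 at the preset was 0.219 with an estimated correlation, and 0.0518 without STAT3cKO 3. Retnla, a secreted marker of alternatively activated macrophages that fat tissue also makes, fell by 3.10 (SE 0.54, limma adjusted p = 0.0186), a call that held in 6 of the 10 fits and was lost without WT 2, WT 3, WT 5 or STAT3cKO 3 (adjusted p up to 0.0684). Alox15, a lipoxygenase of macrophages and eosinophils, had a value of 8.80 ± 1.05 in WT and no read in 4 of the 5 STAT3cKO libraries (limma adjusted p = 0.0277). Its call held in 3 of the 10 fits, with a highest adjusted p of 0.118 without WT 1. The interleukin 17 and 23 list (5 tested, 0 calls, median 0.62, camera adjusted p = 0.168) and the interferon list (18 tested, 0 calls, median −0.74, camera adjusted p = 0.522) did not pass. In them Zc3h12a had a change of 3.27 (limma adjusted p = 0.418) and Stat2 one of 2.62 (limma adjusted p = 0.50), each with no read in WT 3.

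Of 18 adipocyte genes 1 fell over all genes, Car3, a carbonic anhydrase abundant in fat, with a change of −3.06 (SE 0.56, limma adjusted p = 0.0209), while 16 were lower adjusted over the list alone and 0 of 18 had a positive change. The median was −2.27 (camera adjusted p = 5.01e-16 at the preset, 0.133 with an estimated correlation, and 0.0356 by fry). The call of Car3 held in 5 of the 10 fits, with a highest adjusted p of 0.0729 without WT 1. The adipocyte list mean was 12.9, 13, 12.7, 10.8 and 11.4 in WT 1 to 5 and 9.07, 10.5, 8.58, 10.5 and 9.04 in STAT3cKO 1 to 5. Skeletal muscle genes had 0 calls among 19 and a median of −1.50 (camera adjusted p = 6.81e-05 at the preset and 0.435 with an estimated correlation).

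Of 18 macrophage and monocyte genes 0 passed over all genes and 1 was lower adjusted over the list alone. The median was −0.68 and the change was positive for 1 of 18. The camera adjusted p was 0.00968 at the preset and 0.435 with an estimated correlation, and the call was lost without STAT3cKO 1 or STAT3cKO 3 (adjusted p up to 0.339). Lyz2, the lysozyme of myeloid cells, had a change of −2.0 (limma adjusted p = 0.10). Of 11 antigen presentation genes 0 passed and 2 were lower adjusted over the list alone, with a median of −1.39 (camera adjusted p = 0.00575 at the preset and 0.358 with an estimated correlation). H2-Aa, a class II antigen-presenting chain, had a change of −2.52 (limma adjusted p = 0.0592). The lists of T and NK cells (5 tested, median −3.32, camera adjusted p = 0.0940) and mast cells (8 tested, median −0.26, camera adjusted p = 0.453) had 0 calls. Neutrophil, B cell and sex-specific lists had 3, 1 and 1 tested members and were not tested as sets, and 0 of these members were called.

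Of 20 fibroblast genes 1 fell, Dpt, the matrix protein dermatopontin, with a change of −1.53 (SE 0.33, limma adjusted p = 0.0287), with 2 lower adjusted over the list alone, a median of −0.34 and a camera adjusted p of 0.0940. The call of Dpt held in 3 of the 10 fits, with a highest adjusted p of 0.0997 without WT 1. Endothelial (14 tested, median 0.28, camera adjusted p = 0.182), smooth muscle (10 tested, median −0.20, camera adjusted p = 0.417), Schwann cell (9 tested, median 0.52, camera adjusted p = 0.140) and melanocyte genes (5 tested, median 0.39, camera adjusted p = 0.365) had 0 calls. Erythrocyte genes (8 tested, 0 calls, 1 higher adjusted over the list alone, median 0.84) had an adjusted p of 0.0172 at the preset and 0.429 with an estimated correlation. It was 0.454 without STAT3cKO 2, which held the most Hba-a1, and the call was also lost without WT 2.

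Hair shaft and inner root sheath genes, which follicles make while a hair grows, differed widely within both groups. Their mean was 2.47, 2.58, 5.76, 14.1 and 4.13 in WT 1 to 5 and 10.6, 1.41, 13.9, 2.25 and 10.5 in STAT3cKO 1 to 5. The 13 tested members had 0 calls, a median of 2.16 and an adjusted p of 0.0438 at the preset, which was 0.545 with an estimated correlation. The call was lost without WT 1, WT 2, STAT3cKO 1, STAT3cKO 3 or STAT3cKO 5 (adjusted p up to 0.503). With this mean as a covariate 80 genes rose and 73 fell, 59 and 51 of them among the 61 and 53.

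Of 11 genes of follicle stem cells and the outer root sheath 1 rose, Krt79, a keratin of the upper follicle, by 2.67 (SE 0.35, limma adjusted p = 0.000460). The median was 0.31 (camera adjusted p = 0.111). Of 15 sebaceous gland genes 2 rose, 0 fell and 13 did not pass, with 3 higher and 1 lower adjusted over the list alone. The risers were Soat1, which esterifies cholesterol, by 3.10 (SE 0.47, limma adjusted p = 0.00167) and Elovl3, a fatty acid elongase, by 4.31 (SE 0.61, limma adjusted p = 0.00355). The list's median was 0.44 and its mean −0.16, and its camera adjusted p of 0.0438 was 0.429 with an estimated correlation. It was also lost without WT 4, STAT3cKO 1, STAT3cKO 2, STAT3cKO 4 or STAT3cKO 5 (adjusted p up to 0.266). Elovl3 was also the 1 riser among 6 brown adipocyte genes, a list with a median of −0.27, a mean of 0.30 and a camera adjusted p of 0.291, whose median turned positive in part of the other scalings. Exons of Elovl3 overlap those of Pitx3 on the other strand.

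**Figure D2:**
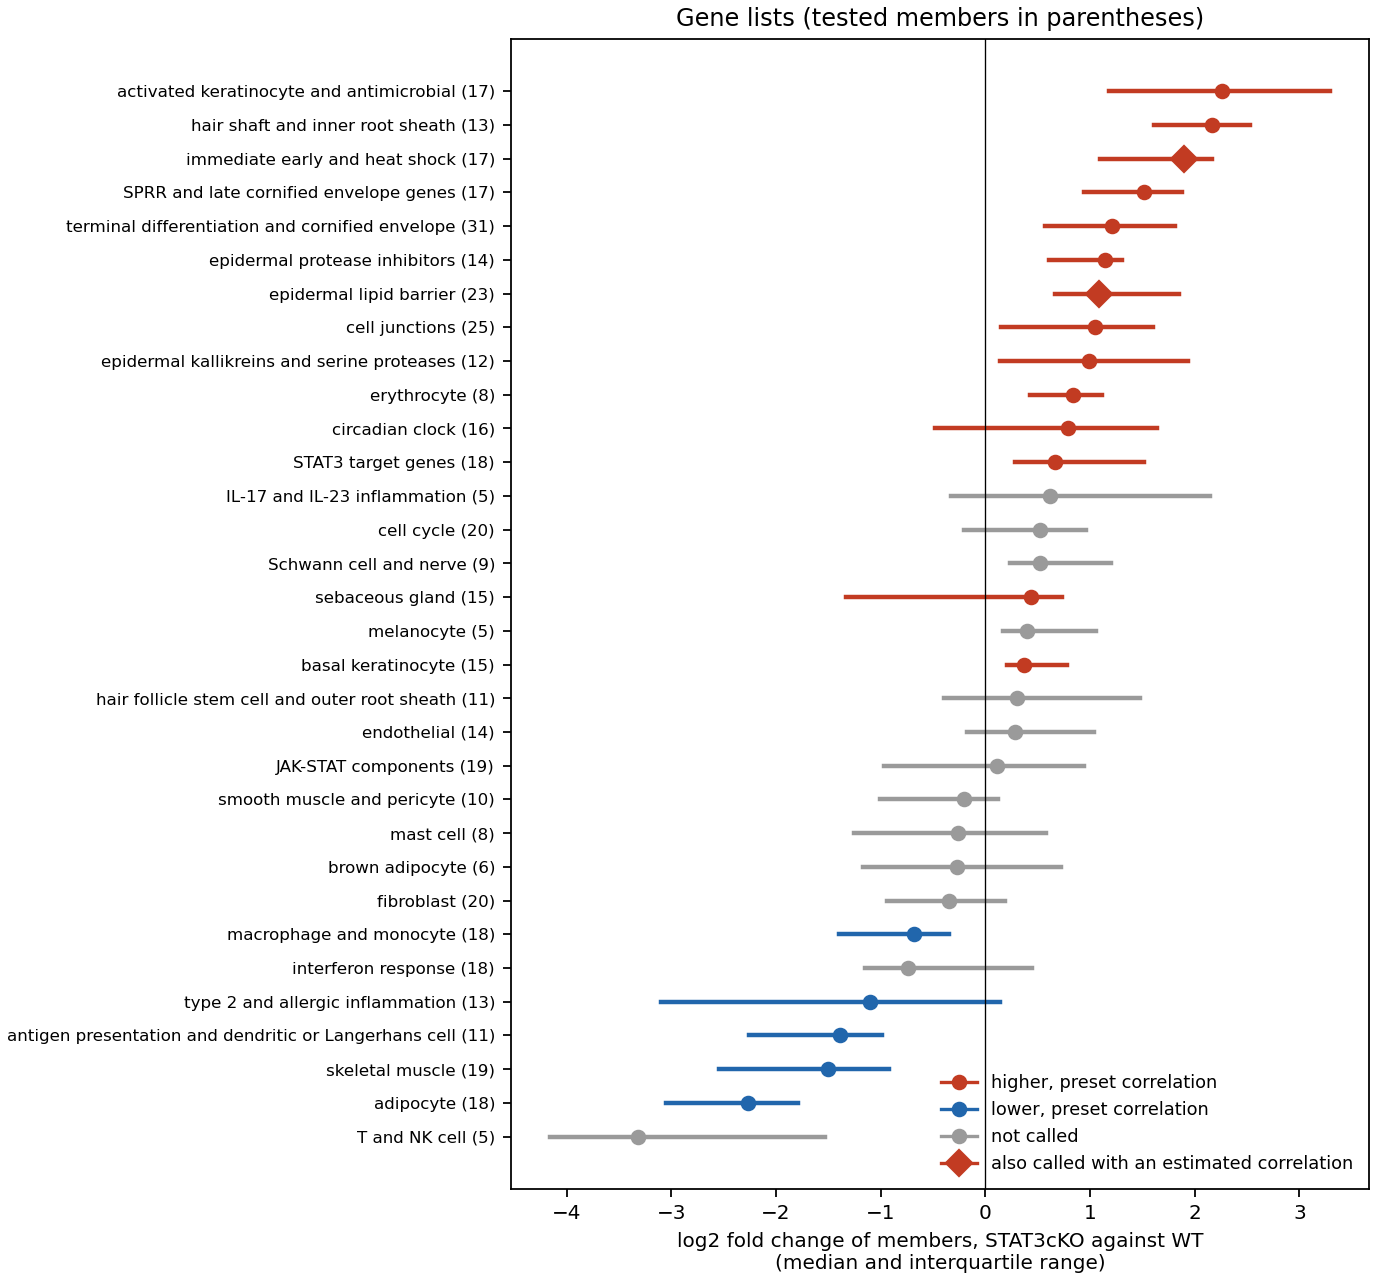
Median (point) and interquartile range (line) of the log2 change, STAT3cKO minus WT, on the x axis over the tested members of each of the 32 lists, with lists called at the preset correlation in colour and the 2 also called with an estimated correlation as diamonds. The medians run from −3.32 for T and NK cell genes to 2.26 for activated keratinocyte genes.

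**Figure D3:**
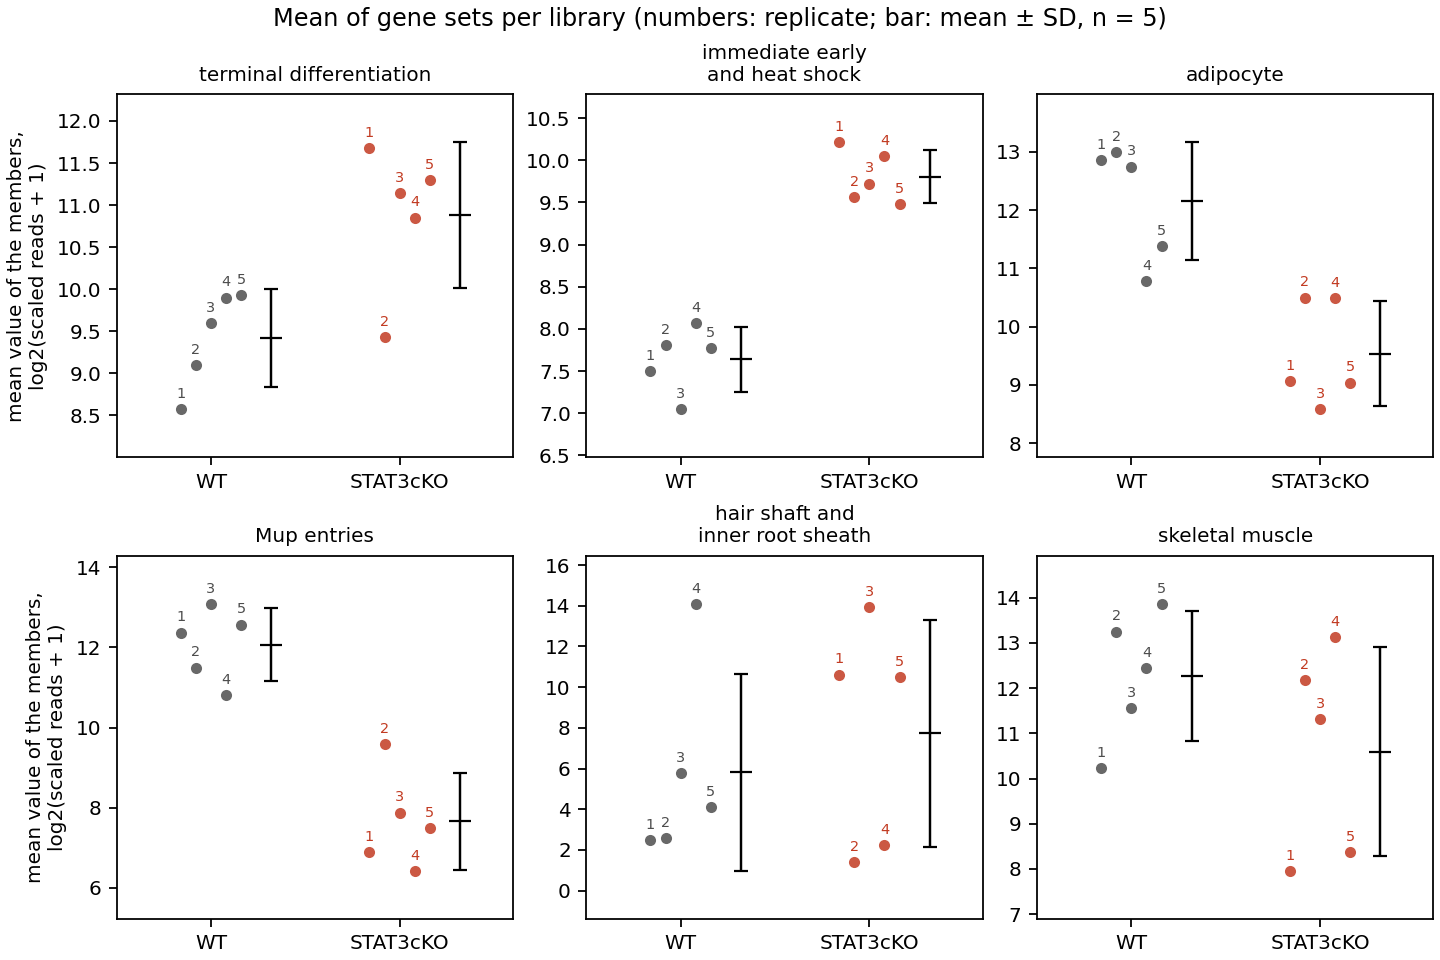
Mean deposited log2 value of 6 gene sets on the y axis in each library, 1 point per library with its replicate number, WT beside STAT3cKO, with the group mean ± SD (n = 5) as a bar. The adipocyte means of STAT3cKO lay at 8.58 to 10.5 and those of WT at 10.8 to 13, while hair shaft means spread from 1.41 to 14.1 over both groups.

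Large falls were seen in the major urinary protein (Mup) genes, which encode lipocalins that bind pheromones and small lipids. The files hold 22 Mup entries, counting entries under predicted names. The Mup genes of the annotation all lie in 1 cluster on chromosome 4 (59956804 to 62150863), while the entries under predicted names were not placed in it. Of 19 tested 16 fell, with a median of −4.73 and a range of −4.95 to −1.04 over the 19. Mup9, Mup19, Mup14, Mup8 and Mup16 fell, with changes of −4.95, −4.88, −4.88, −4.83 and −4.82, and the mean over all tested Mup genes was 12.1 ± 0.905 in WT and 7.66 ± 1.22 in STAT3cKO (SD, n = 5 each). The copies are nearly identical, so reads of one can be counted for another and the single entries are uncertain. Without them 37 genes fell.

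Rnase2a, an eosinophil-associated ribonuclease, had a value of 9.42 ± 1.28 in WT and no read in any of the 5 STAT3cKO libraries (limma adjusted p = 0.00226). Serpinb6e, a serine protease inhibitor, had 8.35 ± 1.37 in WT and no read in any STAT3cKO library either (limma adjusted p = 0.0105, and 0.0606 without WT 2). Ifitm6 had no read in 3 STAT3cKO libraries, against 8.13 ± 1.41 in WT (limma adjusted p = 0.0495), and was called in 1 of the 10 fits without a library, with a highest adjusted p of 0.134 without WT 3. Cd209g, a lectin, fell by 5.09 (limma adjusted p = 0.0403) and was called in 4 of the 10, with a highest adjusted p of 0.151 without WT 1. Pnpla3, a lipase-like protein of fat and liver, and Aoc3, an amine oxidase of adipocytes and vessels, both chosen after their values were seen, fell, with changes of −4.29 (SE 0.54, limma adjusted p = 0.000303) and −3.45 (limma adjusted p = 0.0186). The call of Pnpla3 held in all 10 fits and that of Aoc3 in 7.

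Further large rises were those of Cyp1a1, a target of the aryl hydrocarbon receptor, by 3.79 (SE 0.79, limma adjusted p = 0.0248), and Panx3, a channel protein, by 3.46 (SE 0.79, limma adjusted p = 0.0405). Acot5, an acyl-CoA thioesterase, had a value of 1.62 ± 2.95 in WT, with no read in 3 libraries, and 9.04 ± 0.96 in STAT3cKO (limma adjusted p = 0.0341). Mettl17 likewise had no read in 3 WT libraries and went from 0.95 ± 1.47 to 7.58 ± 0.72 (limma adjusted p = 0.0495), but its exons overlap those of Slc39a2 on the same strand. These calls were fragile when 1 library was left out. That of Cyp1a1 was lost without STAT3cKO 4 or STAT3cKO 5 (adjusted p up to 0.0918), and Panx3, Acot5 and Mettl17 were called in 3, 2 and 1 of the 10 fits, with highest adjusted p-values of 0.155 without STAT3cKO 1, 0.103 without STAT3cKO 4 and 0.147 without WT 2.

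**Figure D4:**
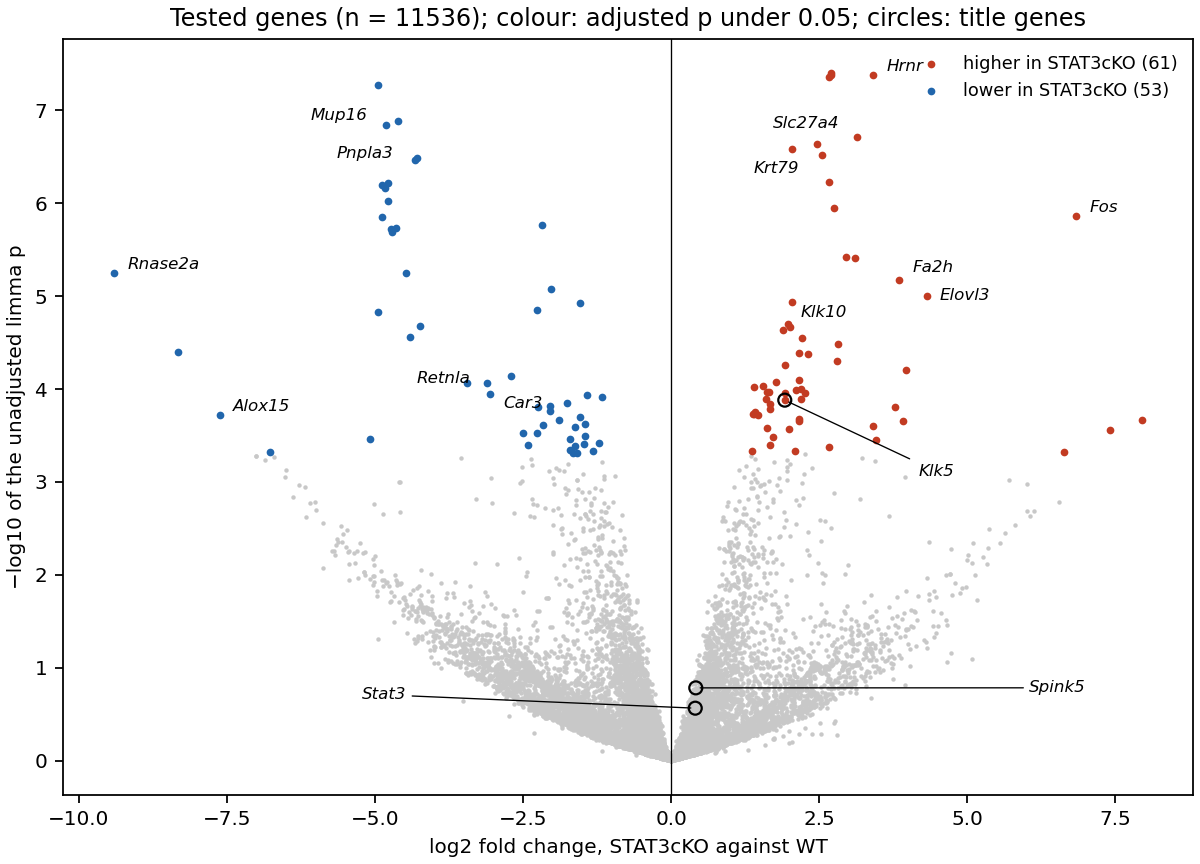
Log2 change (STAT3cKO minus WT) on the x axis and −log10 of the unadjusted limma p on the y axis, 1 point per tested gene, with the 61 higher and 53 lower genes coloured and the genes of the study's title circled. Klk5 lies among the coloured points at 1.92, and Stat3 and Spink5 lie near the bottom at 0.41 and 0.42.

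Of the 114 called genes 57 higher and 46 lower ones had groups without overlap. Over all tested genes that held for 395, or 3.42%, against 0.794% expected by chance. At an unadjusted p under 0.05 there were 1257 genes, against 576.8 expected by chance. Within the 4 deeper libraries 60 genes rose and 72 fell and within the 6 shallower ones 10 rose and 4 fell. Of the 35 named genes that were called 16 kept their call with each library left out. The median change of all tested genes was −0.16, and reported changes were not corrected for it. Without STAT3cKO 2 it was 0.05, and without any other single library it ranged from −0.25 (without WT 3) to −0.10 (without WT 2). Without both STAT3cKO 2 and WT 3 the median was −0.029, so its sign depends on which libraries are used. After quantile normalization the median was −0.00637 and the change of Klk5 was 1.91.

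Of the 32 tested lists 14 were higher and 5 were lower at the preset correlation. With an estimated correlation 2 of them held, the lipid barrier and the immediate early list. By fry 4 passed, the same 2 (adjusted p = 0.00453 and 0.000385) and the terminal differentiation and adipocyte lists. Exact permutation tests of each list's mean per library gave 0.0873 as the smallest adjusted p. The type 2, immediate early and adipocyte lists had the smallest exact p that this test can give, 0.00794. After adjustment over the lists the test could thus hardly pass any of them, and it decides little. Exons of 26 of the called genes overlap those of another gene, on the other strand for 22, and Pet100 and Pcp2 on chromosome 8 are such a pair in which both were called. Slurp1 and Cers4 are also among them, with overlaps on the other strand, and so is Pnpla3, with 1 on the same strand. The near-identical copies Tmem254a, Tmem254b and Tmem254c were called together, so their 3 calls are uncertain as well.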

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

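Chosen after the result was seen were the tests on the Mup genes and those on the epidermal and fat lists, while the tests on the immediate early genes and on other splits of the libraries had been written down first.

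Dixon's test looked within each group of 5 libraries for a library whose gap to its nearest neighbour exceeds 0.71 of the group's whole range. It was applied to depth, genes without a read, the share of the 10 top genes, list means, Ddx3y and genes chosen by the rule. Other genes named outside the rule and the Mup means were not searched. Chance marks about 1 in 20 groups, or 11.5 of the 230 searched here, and 21 were found, of which 7 lay in WT 4, 6 in STAT3cKO 2 and 4 in WT 3. In STAT3cKO 2 the 10 most abundant genes took 10.4% of the scaled reads (5.98 to 7.01% in the other STAT3cKO libraries), the circadian list mean was 6.09 (7.47 to 7.88), Hba-a1 stood at 17.37 (14.44 to 15.10) and Cd209g had no read, at 0.064 (5.5 to 7.38). The same library had Xist at 0.064 (8.65 to 10.25) and Ddx3y at 10.62 (0 to 1.06). In WT 4 the hair shaft list mean was 14.1 (2.47 to 5.76 in the other WT libraries), that of T and NK cell genes 3.55 (6.23 to 7.16), and Dct, a pigment gene, stood at 12.93 (6.84 to 7.74). Fa2h at 8.155 (10.68 to 11.21), Retnla at 12.41 (14.39 to 15.15), H2-Eb1 at 10.54 (12.10 to 12.46) and Cd7 at 5.20 (8.04 to 8.83) were low there. WT 3 had no read of Stat2, Tek and Mal, each at 0.057, where the other WT libraries had at least 6.53, and had Nfkbiz at 1.26 (7.10 to 8.37). WT 2 had Egr2 at 6.15 (8.31 to 9.11), and WT 1 held Acot5 at 6.835 (0 to 1.15). STAT3cKO 5 was alone in its group with reads of Alox15, at 5.81, and of Mmp9, at 6.92.

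The counts of calls were set against other ways to divide the 10 libraries into 5 and 5. Of 100 of the 126 possible divisions, the real one included, 1 gave as many calls, the real one itself, with 114 genes against 46 in the highest of the others. The same held for genes higher (61 against 31) and lower (53 against 31), again for 1 of the 100, and 88 of the 100 called 0 genes. For gene lists at the preset correlation 1 of the 100 reached 19, but the highest other reached 18. At 1 of 100 divisions chance is an unlikely source of the gene counts, though it is not excluded. For the lists the rule set beforehand against chance was met as well, at 1 of 100 divisions. The distance to the highest other division was narrow and the preset test is liberal in these data, so no conclusion is drawn from it.

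The terminal differentiation list was called higher and the adipocyte list lower at the preset correlation, but neither with an estimated one, and a shift in what each piece of skin held could be behind both. Less fat as the whole cause would raise all other cell types alike, but the terminal differentiation mean rose over the fibroblast mean by 1.88 (exact permutation p = 0.00794, n = 5 each). That argument holds only if fibroblast genes are not lost together with the fat, which was not tested. More epidermis as the whole cause would raise basal and differentiated genes alike, but the terminal differentiation mean rose over the basal mean by 1.08 (exact permutation p = 0.00794). Basal genes are also made in follicles, so the share of epidermis between follicles stays open. The basal list did not move as 1 either: Krt14 had a change of 1.30 and Itgb1 one of −0.87, with 13 of 15 members positive. Whether other cells of the skin made part of this list was not tested, so a larger epidermal share is not excluded. Hair growth as the whole cause would leave little after adjustment, but with the hair shaft mean as a covariate the terminal differentiation mean still differed by 1.27 (permutation p = 0.0317), against 1.46 without it, and the adipocyte mean by −2.30, against −2.62. Sex as the whole cause would leave no difference among the 9 libraries with Xist, but among them the terminal differentiation mean differed by 1.82 (exact permutation p = 0.00794, 4 STAT3cKO and 5 WT) and the adipocyte mean by −2.86 (exact permutation p = 0.0159). Fat, epidermis, hair growth and sex were each tested as the whole cause only, so a partial or joint share of them stays open. Also open are an effect of keratinocyte STAT3 loss on differentiation and on skin fat, the depth of the dissected skin, and differences in harvest that the sources used here do not give.

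Immediate early genes rose with Fos in the lead, as they may after handling of tissue as well as after signalling in the animal. A higher share of keratinocytes as the whole cause would raise them no more than keratinocyte genes, but their mean rose by 1.06 more (exact permutation p = 0.0476, n = 5 each). The keratinocyte genes joined the basal list, whose mean was higher by 0.38, and the terminal differentiation list, higher by 1.46. The immediate early mean was higher by 2.17. A comparison with the terminal differentiation list alone was not tested, so the result depends on the reference chosen. The 5 heat shock members of the list, which warm or slow handling would be likely to raise, had a median change of 0.23, too small to speak for handling and not low enough to exclude it. Genotype and handling cannot be told apart here, because the time from death to extraction is not given for any library.

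The fall of the Mup genes could follow from less fat, since skin fat makes Mup transcripts. As the whole cause this would move Mup and adipocyte genes alike, but the Mup mean fell beyond the adipocyte mean, with a difference of −1.79 (exact permutation p = 0.0317, n = 5 each). The abundant fat genes Cfd, Fabp4 and Adipoq had changes of −2.45, −2.26 and −3.04, and Pnpla3 and Aoc3 had −4.29 and −3.45, against a Mup median of −4.73. These single genes were all chosen after their values were seen. Whether part of the fat genes falls as far as the Mup genes was not tested and stays open. Reads shared between the copies could be the source of the number of calls: deviations of the tested Mup entries within groups had a median pairwise r of 0.78, which shared reads and shared regulation both give, and these cannot be told apart. Mup genes are also known to respond to sex and growth hormone, and STAT3cKO 2, which carried Ddx3y but no read of 3 other Y genes and none of Xist, had the highest Mup mean of its group, 9.60, still below the lowest WT mean of 10.8. Sex as the whole cause would leave no difference among the 9 libraries with Xist, but their Mup mean differed by −4.89 (exact permutation p = 0.00794).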

How the results depend on the processing

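Chosen after the result was seen were the pseudocounts of 10 and 100, the filter at 7, quantile normalization, the depth and hair shaft covariates, and the fit without STAT3cKO 2 and WT 3. The 61 higher and 53 lower genes became 202 and 173 with array quality weights, 123 and 126 with a pseudocount of 100, 98 and 83 after quantile normalization, and 21 and 22 at an adjusted p under 0.01, where the stricter threshold is the cause. For the other settings the cause was not tested. With the replicate number as a block they became 34 and 32 (30 and 25 of them shared), and Klk5 kept its change of 1.92 at an adjusted p of 0.0964. The sources used here do not say that the numbers pair the libraries, and the values gave no sign of it. Deviations of same-numbered libraries had r of 0.016, −0.030, −0.017, −0.155 and −0.109, and for each number a library of another number gave a higher r. Since the highest of several other r was taken, this does not exclude a pairing. Without STAT3cKO 2 and WT 3 the counts were 56 and 37 (42 and 28 shared) and the change of Klk5 was 2.01, with an adjusted p that rounds to 0.05 but lies just above it.

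Leaving out 1 library moved the higher count from 30 (without STAT3cKO 1) to 101 (without WT 4) and the lower count from 24 (without WT 2) to 117 (without WT 4). Counts also moved by over 1.5 times without WT 1 (38 and 25), WT 2 (37 higher), WT 3 (25 lower), STAT3cKO 1 (33 lower), STAT3cKO 4 (38 higher) and STAT3cKO 5 (36 higher). In all 10 such fits 25 of the higher and 22 of the lower genes passed. Lists lower ranged from 3 (without STAT3cKO 3) to 6 (without WT 4 or STAT3cKO 5), and lists higher from 11 to 17. The change of Klk5 ranged from 1.66 (without STAT3cKO 1) to 2.09 (without WT 5). Over all 24 alternatives it passed in 19, with adjusted p from 0.00195 to 0.0964. Stat3 (0.24 to 0.62) and Spink5 (0.26 to 0.67) passed in 0 of 24.

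None of the called genes named by the rule changed direction under the alternatives run, and of the called lists 1 did: the sebaceous median ranged from −0.0092 (without WT 4) to 0.55 (without STAT3cKO 3) with 1 library left out. The sebaceous call was also lost after quantile normalization, with either pseudocount, with the block and without STAT3cKO 2 and WT 3. Type 2 and erythrocyte calls were lost with array quality weights and without those 2 libraries. With the filter at 7 the circadian, hair shaft and erythrocyte calls were lost, and with the hair shaft covariate that of macrophage and monocyte genes. The cell cycle list, not called in the main fit, passed in 10 of 24. The median of all genes moved from −0.16 to −0.00637 after quantile normalization. DESeq2's Wald test was not run, since the values are not counts.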

Other observations

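The cholesterol and macrophage genes described here were noticed among the called genes, and the genes that were noticed were left out of the tests. The tests themselves had been written down before their results were seen.

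Cholesterol synthesis genes stood out among the rises outside the fixed lists. Msmo1 and Cyp51, enzymes of the late steps from lanosterol to cholesterol, rose by 2.46 (SE 0.30, limma adjusted p = 0.000294) and 2.55 (SE 0.32, limma adjusted p = 0.000303), and both calls held with any 1 library left out. Tmem97, Dhcr7, Lss, Pmvk and Hsd17b7 rose as well, by 2.32, 1.55, 2.19, 1.62 and 2.09, and were called in 10, 7, 7, 2 and 3 of the 10 fits that each left out 1 library. A hypothesis is that the pathway rose as a whole, and it was tested on 19 further genes of cholesterol synthesis and uptake that had not been noticed. Of the 17 tested, 13 had a positive change, the median was 0.83, and 11 were higher and 1 was lower adjusted over the list alone. That 0 passed over all genes says little, since the genes left out had been noticed because they were called. Camera with an estimated correlation gave p = 0.0205, which suggests that the rise reached beyond the genes first seen. The member lower adjusted over the list alone was Insig1, itself a sterol-responsive gene, at −1.31, and Srebf2, the pathway's transcription factor, had a change of −0.55 (SE 1.91). The exons of Cyp51 and Lss overlap those of genes on the other strand.

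A larger share of sebaceous gland, a tissue rich in sterol synthesis, could be the source. The mean of the further cholesterol genes rose over the sebaceous list mean by 1.12 (exact permutation p = 0.0317, n = 5 each), which was the bound set beforehand against this explanation. That bound was poorly chosen, because the sebaceous list does not move as 1: its median change was 0.44 and its mean −0.16. Soat1 stood at 3.10 and Elovl3 at 4.31, but Scd3, chosen after its value was seen, at −6.71 (limma adjusted p = 0.0520). The 2 explanations therefore stay open.

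Lower genes included markers of tissue-resident macrophages of the dermis. Retnla, Cd209g, Wfdc17 and Cbr2 fell, with changes of −3.10, −5.09, −2.16 and −1.71 (limma adjusted p = 0.0186, 0.0403, 0.0317 and 0.0489), and were called in 6, 4, 4 and 2 of the 10 fits that each left out 1 library. Among 19 further genes of this cell type, all tested, 18 had a negative change, the median was −0.79 and 5 were lower adjusted over the list alone. Here too, that 0 passed over all genes says little, since the called ones had been left out. The 5 were Ltc4s, Mgl2, Cd209d, Gas6 and Folr2, with changes of −5.45, −4.57, −1.98, −1.46 and −1.41. Of the 3 most abundant in WT, Mrc1 and F13a1 had changes of −0.57 and −0.05, and the other was Gas6. Camera with an estimated correlation gave p = 0.179, so the hypothesis of a fall in these macrophages as a whole did not pass its test and stays open.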
